A study of Mus musculus with 3 samples.

How the data were processed

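Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts open chromatin and inserts sequencing adapters, so that read density marks accessible DNA. The 3 samples were mouse prostate lobes taken 6 weeks after deletion of the tumour suppressor gene Pten. They are named AP, DLP and VP, and their labels give the cell type as the antero-dorsal, the distal and the ventral lobe. There was 1 library per lobe, and no library from prostate with intact Pten was analysed here. All differences between lobes are therefore differences between single libraries, with no replicate check, no standard deviation and no p-value.

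Per the labels' protocols, nuclei were released with a detergent buffer, incubated with transposase for 30 min at 37 °C, and the amplified libraries were size selected. The submitters' processing notes name Bowtie2 2.2.6, SAMtools, Picard, MACS2 2.1.0.20151222, HTSeq and HOMER, and the genome builds GRCm38 and mm10, without saying what each tool did. The shift of reads to the transposase cut, the removal of duplicates, the counting window and the peak threshold are not given in the sources used here. The deposited table lists peaks with merged identifiers, so all libraries share 1 peak set. Each peak carries 1 or more gene names and a whole-number value per library. Of the value columns, 2, named AP3 and DLP3, matched no sample given here and were not used in any step. What they hold is not given in the sources used here. Coordinates are as deposited, and whether starts count from 0 or 1 is not given in the sources used here.

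The deposited values are treated as a score, meaning a read density that the authors had scaled and rounded. They are not raw counts. The totals over peaks lay within 1.31% of each other, and the AP values fell on a comb of favoured and avoided whole numbers, as rounded multiples of a fixed step do. A step of 0.391 score units fitted the AP comb, lowering the residual by a factor of 9.77 against a smooth histogram. This step was taken as the worth of 1 AP read, which puts about 2320910 reads in the listed AP peaks. For DLP and VP the residual was lowered by factors of only 1.81 and 2.05, below the factor of 5 required, so the depth of those libraries is unknown. On simulated libraries of 66961 peaks, steps of 0.21, 0.391, 0.6 and 0.9 were recovered in 5 of 5 draws each, and steps of 0.11 and 1 in 0 of 5.

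The table held 95557 pairs of a peak and a gene, which make 66961 different peaks with a median width of 548 bp. Scores were analysed as log2(score + 1) as deposited, with no further scaling, so that fold differences are on that scale and understate changes at low scores. Peaks were kept where the highest of the 3 scores exceeded the 10th percentile, a score of 2, which left 60013. A peak was called higher in a lobe when its log2 value was at least 1 above both other lobes, that is at least 2-fold. Pairwise calls needed the same distance between 2 lobes. The counts that counting error alone would give were simulated 100 times with no difference between lobes, with 1 read worth 0.391 or 1 score unit in every library. Such simulations and the intervals for single scores cover counting error only. A step of 0.391 was recovered in 5 of 5 simulated libraries but not in DLP or VP, so those lobes are unlikely to have the AP step. Counts set against the AP step therefore describe that setting only. The setting of 1 unit gives AP a coarser step than the 0.391 fitted to it, so it overstates counting error in AP. With planted differences, the calling step recovered 43 of 200 peaks at 2-fold, 197 of 200 at 3-fold and 200 of 200 at 4-fold in VP against the other lobes, among 58100, 58087 and 58030 kept peaks and with the AP step. With 1 read worth 1 unit it recovered 60, 170 and 199 of 200. Differences were planted only in peaks with a highest score of at least 10, so these rates do not cover weaker peaks.

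Gene symbols were matched to the RefSeq annotation of GRCm38.p6, which held 98.7% of the 16972 symbols. That table gives gene spans without strand, so distances to transcription start sites could not be computed. In their place, a gene's peaks were those the deposited table assigns to it within 50 kb of its annotated span, and a peak counted as near a gene end when it lay within 1 kb of either end of an assigned gene. A peak assigned to neighbouring genes counts for each of them. Exons, introns and UTRs were not annotated here, and motif content and GC content were not computed, as no genome sequence was used here.

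A total of 23 gene lists were examined in the 3 pairwise comparisons. The cell type markers covered basal epithelium, luminal epithelium, proximal progenitor-like luminal cells, lymphocytes, myeloid cells, fibroblasts, smooth muscle, endothelium, neuroendocrine cells, seminal vesicle epithelium and urothelium. The functional lists covered lobe-restricted secretory genes, posterior Hox genes, developmental transcription factors and signals, NF-kB pathway and target genes, innate immune sensing, interferon response, mucosal defence, AP-1 and immediate early genes, the PI3K-AKT pathway, androgen-regulated genes, mesenchymal plasticity genes and ubiquitous promoters as a control. A gene's value was the mean log2 difference of its peaks, and a list's value was the median over its genes. Each median is given with its percentile among 10000 random lists of equal size matched on mean signal and number of peaks, drawn from 16212 genes. Percentiles outside the central 95% are reported as standing apart, as a description of these libraries. In simulations on VP minus AP over 16212 genes, 3 of 50 lists with no shift fell outside that range, and 50 of 50 lists of 20 genes shifted by 0.3 on the log2 scale lay above it. Those simulations held counting error at the AP step only, so their rates do not carry over to these libraries or to shorter lists. In VP minus DLP, larger distances from the random median stayed inside the range: -0.35 for 10 myeloid genes and 0.47 for 9 fibroblast genes.

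Named genes followed a rule with 4 parts. For each lobe, the 8 genes with the most peaks higher in that lobe were named, ties being ordered by the summed log2 difference to the next lobe. For each lobe, up to 5 peaks with the largest log2 difference to the next lobe were named among the top decile of that lobe's scores. For each list, up to 2 genes with the highest and 2 with the lowest difference in a pairwise comparison were named. Pten, Krt5, Krt14, Trp63, Krt8, Krt18, Nkx3-1, Ar, Hoxb13, Foxa1, Psca, Tacstd2, Krt4, Nfkb1, Nfkb2, Rela, Relb, Nfkbia and Tnfaip3 were always named. The comparisons, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were other scalings (equal totals, median of ratios, control promoters), removal of a trend with signal, pseudocounts of 0.1 and 5, no filter or a filter at the 50th percentile, thresholds of 1.5-fold and 4-fold, and other ways to assign peaks to genes. Added after the data were seen were a minimum score of 20, the 3 kb limit around gene ends, the comparison of gene-end shares with peaks of like signal, drawn from 50 bins of mean log2 score or 30 of highest score, and, for the gene lists, quantile-normalized values, a pseudocount of 5, scaling by median of ratios or to control promoters, and counting each peak for its nearest gene alone. Quantile-normalized values were also added for the pairwise counts. Symbols that name the same gene were counted once per list. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.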

Results

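Accessible chromatin was profiled by ATAC-seq in the AP, DLP and VP lobes of mouse prostate 6 weeks after Pten deletion, with 1 library per lobe. Pten encodes the lipid phosphatase that opposes PI3K signalling, and the series concerns innate immunity, NF-kB and the plasticity of prostate stem cells. The values are the authors' scaled and rounded scores over a shared set of 66961 peaks. Total scores were 907477 in AP, 895765 in DLP and 903871 in VP, and the median peak score was 6, 7 and 6. With 1 read worth 0.391 score units, as found for AP, counting error alone spread a log2 difference by 0.78 at a score of 10, 0.55 at 20, 0.39 at 40 and 0.25 at 100 (95% half-range). With 1 read worth 1 unit the half-range was 1.25, 0.88, 0.63 and 0.40. Several counts below lay under the mean of that simulation, such as 1541 peaks lower in DLP than in AP against 6176. That count also lay under the mean of 1871 with the AP step, so it alone does not tell which step is nearer the true error. For AP the fitted step of 0.391 does, and 1 read worth 1 unit overstates counting error in that library. For DLP and VP the worth of 1 read is unknown. The Pten region itself held 4 kept peaks, of which the strongest lay at a gene end (chromosome 19, 32755730 to 32757868) and scored 104 in AP, 85 in DLP and 110 in VP. The labels do not say which part of the gene was deleted, so this peak does not check the deletion.

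The 3 lobes shared most of their accessible regions, and DLP and VP lay furthest apart. Across the 60013 kept peaks, which are not independent replicates, the Pearson correlation of log2 scores was 0.912 between DLP and AP, 0.906 between VP and AP and 0.850 between VP and DLP. Spearman's coefficients were 0.895, 0.891 and 0.823. Of the 14788 peaks at least 2-fold apart between VP and DLP, 68.4% had an AP score strictly between the others. Choosing peaks with 2 lobes apart favours this order: counting error alone gave 55.5% with the AP step and 47.1% with 1 read worth 1 unit. DLP lay between the others in 34.5% of the peaks that separated VP and AP, and VP in 30.7% of those that separated DLP and AP. At a highest score of at least 20 the AP share was 90.2% of 1310 peaks, and the DLP and VP shares were 32.5% and 28.01%. Counting error gave an AP share of 89.7% with the AP step and 76.4% with 1 read worth 1 unit. The 89.7% comes from few peaks: a mean of 4.3 were higher and 4.2 lower in VP than in DLP per simulation. All lobes share 1 mean in those simulations, so their shares are no baseline for the 1310 peaks or for the 14788. DLP stood apart in the weakest peaks. In the weakest decile by mean signal the median score was 2 in AP, 3 in DLP and 1 in VP, whereas in the strongest decile it was 55, 50 and 56. Peaks at 0 numbered 2153 in AP, 296 in DLP and 2913 in VP.

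**Figure D1:**
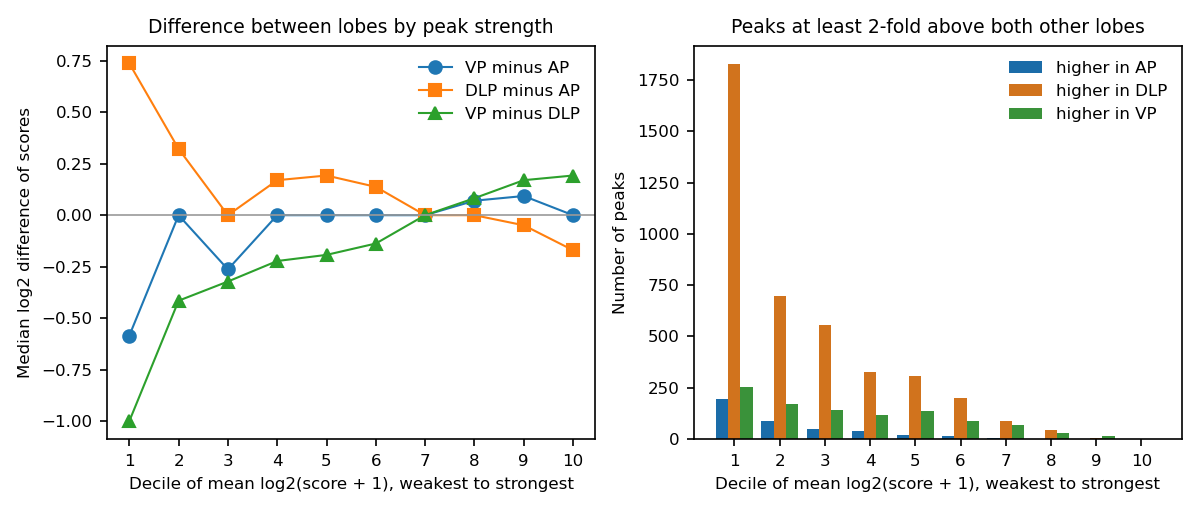
Left, the median log2 difference of peak scores for each pair of lobes (y axis) in 10 deciles of mean log2(score + 1), from weakest to strongest (x axis). Right, bars give the number of peaks at least 2-fold above both other lobes in each decile, with 1 library per lobe. DLP minus AP goes from 0.74 in the weakest decile to -0.17 in the strongest, and 1827 of the 4052 peaks higher in DLP lie in the weakest decile.

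The first question was which regions were more open in 1 lobe than in both others. AP had few such regions. Its largest excess was a peak within Cwc27, which encodes a spliceosome-associated cyclophilin (chromosome 13, 104742788 to 104743144). It scored 350 in AP, 24 in DLP and 37 in VP, 9.24-fold above the next lobe. A peak 10.3 kb from Twsg1, a modulator of BMP signalling, scored 99, 35 and 45 in the same order (chromosome 17, 65961468 to 65962188). A peak assigned to Papd7 and to Srd5a1, a steroid 5-alpha-reductase gene, scored 36, 17 and 12 (chromosome 13, 69563136 to 69564428). No further peak in the top decile of AP scores was higher in AP. Lig3 and Rffl, neighbours that share peaks, and Pid1 had 3 AP-high peaks of 12 each. 4930522L14Rik, Map3k9, Pcnx, Prex2 and Abcc5 had 2 each, Map3k9 and Pcnx being neighbours with shared peaks. Prex2, whose product binds PTEN, had summed scores of only 13, 6 and 4 over 3 peaks. In all, 416 peaks were higher in AP, against a mean of 409.3 and a maximum of 453 in simulations of counting error with the AP step. The total was thus not above counting error at that setting. That total rests on ties: 274 of the 416 lay exactly 2-fold above the next lobe, and scaling to equal totals left 142 and scaling to control promoters 90. At a highest score of at least 20 there were 6, against a simulated maximum of 2 with the AP step and 36 with 1 read worth 1 unit.

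DLP had the most such regions. Mtap, an enzyme gene of methionine salvage, had 11 DLP-high peaks among its 20 kept peaks, with summed scores of 129 in AP, 187 in DLP and 74 in VP. Nos1, the neuronal nitric oxide synthase gene, had 8 of 10 (sums of 41, 107 and 19), and Flt1, a VEGF receptor gene, had 6 of 8 (27, 70 and 15). Bnc1, a basonuclin gene, had 7 of 12 (71, 140 and 65), and Smad3, a mediator of TGF-beta signalling, had 7 of 23 (302, 420 and 235). Slc20a1, Mtss1 and Lrrc8d had 7 each. These were mostly weak peaks: only 1 of the DLP-high peaks of these 8 genes, at Mtap, reached a score of 20. Among strong peaks, one within a gene span and assigned to Ubr2 and Prph2 scored 11 in AP, 42 in DLP and 1 in VP (chromosome 17, 46932906 to 46933778), and one in Myof scored 11, 37 and 1 (chromosome 19, 37959241 to 37960250). Peaks assigned to Agfg1 and Tm4sf20, to Foxp4 and Mdfi, and to Afdn were 3-fold, 2.62-fold and 2.47-fold above the next lobe, the last lying 77.4 kb from the gene. In total 4052 peaks were higher in DLP, against simulated maxima of 456 with the AP step and 2099 with 1 read worth 1 unit. Of these, 1847 lay exactly 2-fold above the next lobe, and 2204 peaks were left with scaling by median of ratios. At a score of at least 20 there were 188, against 1 and 41. After quantile normalization the total was 1486, of which 1478 were among the 4052, and 188 peaks reached a score of at least 20, of which 180 were shared.

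VP took an intermediate place. Kitl, the gene of the KIT receptor's ligand, had 5 VP-high peaks among 16, with summed scores of 97 in AP, 100 in DLP and 153 in VP. Gm10309, Gm5148, Nrp1 and the basement membrane collagen gene Col4a2 had 4 each, among 24, 27, 13 and 20 kept peaks. Mdga2, Cdk5rap2 and Slx4ip had 3 each. Of these 8 genes, Col4a2, Mdga2 and Slx4ip each had 1 VP-high peak that reached a score of 20, and the others had none. All 3 kept peaks of Mdga2 were VP-high, with sums of 7, 11 and 41. The peak with the largest VP excess in the top decile, 6.64 kb from a gene span and assigned to A730049H05Rik and Gm15737, scored 15, 14 and 40 (chromosome 6, 92850107 to 92850850). A peak 55.7 kb from Irs2, an adaptor of insulin signalling, scored 26, 27 and 64 (chromosome 8, 10928148 to 10928987), and one 1.01 kb from Psd2 scored 25, 22 and 63 (chromosome 18, 36015730 to 36017038). Peaks assigned to Slc44a2 and Ilf3 and to Rflna were 2.29-fold and 2.11-fold above the next lobe. In total 1013 peaks were higher in VP, above the simulated maximum of 460 with the AP step. That total was below the 2047 with 1 read worth 1 unit, a setting that overstates counting error in AP. Of the 1013 peaks, 531 lay exactly 2-fold above the next lobe. With scaling to equal totals 601 peaks were left, and with control promoters 557. At a score of at least 20 there were 99, against 2 and 44.

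**Figure D2:**
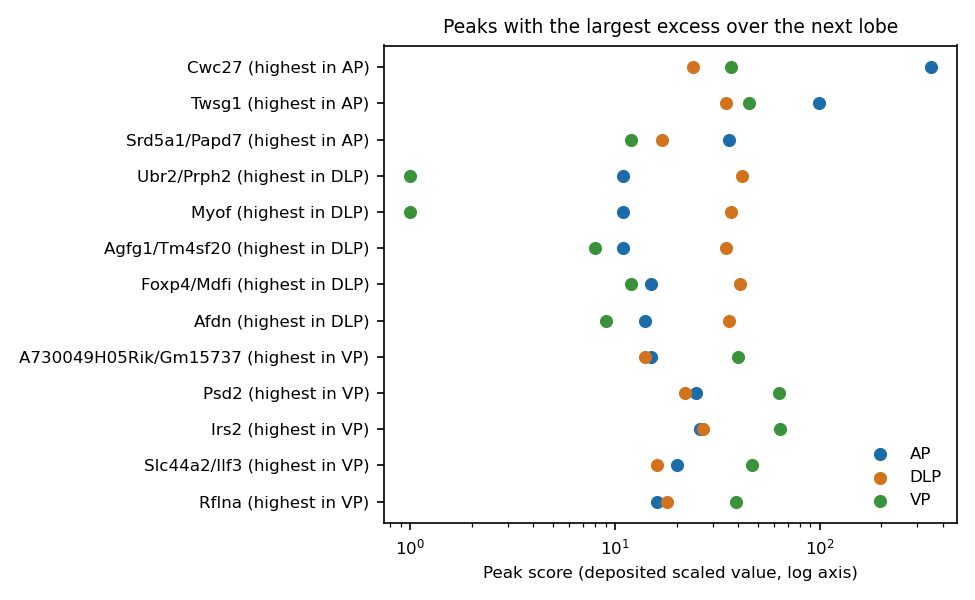
Scores of the 13 peaks with the largest excess over the next lobe among the top decile of scores in AP, DLP or VP, with 1 point per library on a log axis of the deposited score. The Cwc27 peak is the only one with a score above 100, at 350 in AP.

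Peaks higher in DLP or VP lay at gene ends less often than peaks of like signal. Among all kept peaks with a usable gene span, 22.3% lay within 1 kb of either end of an assigned gene (exact binomial 95% interval 21.9 to 22.6). The share was 8.45% (6.0 to 11.6) of peaks higher in AP, 4.85% (4.21 to 5.56) of those higher in DLP and 4.67% (3.45 to 6.16) of those higher in VP. Most lobe-high peaks were weak, and weak peaks lie at gene ends less often. Kept peaks of like mean log2 score that were higher in no lobe had shares of 7.46%, 8.51% and 10.7% in the same order, and those of like highest score 10.8%, 12.7% and 15.5%. The AP-high share was thus not set apart from peaks of like signal. At a score of at least 20 the share was 48.2% of all, 5.32% (2.58 to 9.56) of DLP-high and 7.07% (2.89 to 14.0) of VP-high peaks, and 0 of 6 AP-high peaks, which allows up to 45.9%. Peaks of like mean log2 score had shares of 22.2% for DLP and 27.4% for VP.

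The comparison of VP with AP asked how the VP lobe differed from the AP lobe. Smooth muscle genes were higher in VP than matched genes, led by Acta2, the smooth muscle actin gene, with summed scores of 37 in AP and 82 in VP over 7 peaks (mean fold 1.92), and by the myosin gene Myh11 with 18 and 31 (1.76). The list was mixed, with 4 of 7 genes higher and 3 lower, among them Des (65 and 52) and Myocd (2 and 1). Its median log2 difference of 0.37 lay at percentile 99.9 of random lists, but at 30.5 when the strongest peak of each gene was used. Luminal epithelial genes had 8 of 14 members higher in VP, with a median of 0.09 at percentile 97.8. They included Foxa1, a pioneer factor of prostate epithelium, at 233 in AP and 278 in VP (log2 difference 0.58), and Hoxb13 at 102 and 128 (0.42), while Dpp4 (30 and 18) and Tmprss2 (296 and 269) were lowest. With the strongest peak of each gene that list lay at percentile 51.5. Urothelial genes were lower in VP in 6 of 7 cases, with a median of -0.54 at percentile 1.4. Upk1a had 27 in AP and 18 in VP, and Upk1b had 20 and 12, whereas Upk3a was 1.05-fold higher by mean log2 difference although its summed score was 38 and 32. With peaks at gene ends alone the percentile was 15.7.

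Other lists did not stand apart between VP and AP. Innate immune sensing genes were lower in VP in 24 of 32 cases, with a median of -0.24 at percentile 3.35. Il1rn, the interleukin-1 receptor antagonist gene, had 30 and 10, and Ifih1, an RNA sensor gene, had 29 and 20. This list passed the limit after quantile normalization, at percentile 2.1, and with a pseudocount of 5, at 1.89. Proximal progenitor-like luminal genes had a median of -0.19 at percentile 17.9, or 2.47 with peaks at gene ends alone, with Psca at 15 and 6 and Wfdc2 at 170 and 95. The basal keratin gene Krt14 had 174 and 123 (log2 difference -0.67) and Krt5 had 127 and 120 (-0.23), and the basal list lay at percentile 48.9. Over all kept peaks, 3065 were at least 2-fold higher in VP and 7016 lower, against simulated maxima of 2004 and 1980 with the AP step and 6339 and 6368 with 1 read worth 1 unit. The higher calls made up 30.4%, but 54.2% after removal of the trend with signal, 42.5% with scaling to control promoters and 34.9% with quantile-normalized values. At a score of at least 20 there were 204 higher and 518 lower, and 136 and 518 with the trend removed. Simulated maxima there were 10 and 10 with the AP step and 227 and 233 with 1 read worth 1 unit.

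The comparison of DLP with AP asked how the DLP lobe differed from the AP lobe. Posterior Hox genes, which pattern the hind part of the body axis, were lower in DLP than matched genes. Their median log2 difference was -0.14 in 13 genes, at percentile 0.915. The list stayed outside the central range under 8 of 9 alternatives, but not when each shared peak was counted for its nearest gene alone, at percentile 4.45. The 8 include scaling to equal totals, by median of ratios and to control promoters. Such scaling moves the list and its random lists nearly alike, so staying outside the range under it is no check of the list. Hoxd10 had summed scores of 206 in AP and 133 in DLP over 11 peaks (1.37-fold lower) and Hoxd11 had 196 and 126 over 9 (1.34-fold lower). Hoxd8, with 12 and 18 in a single peak, and Hoxa13, with 75 and 79, were highest. Neighbouring Hox genes share peaks: the list's 81 pairs of a gene and a peak came from 49 different peaks, whose scores summed to 586 in AP, 506 in DLP and 594 in VP. Over those 49 peaks the mean log2 difference of DLP from AP was -0.07, with 25 lower and 18 higher. The random lists take no account of such sharing. With scaling to control promoters, which moved the median DLP minus AP difference of all peaks from 0 to 0.31, the Hox median became 0.14 against 0.38 for random lists, at percentile 0.775. The sign of the difference thus depended on scaling, and its place among random lists on how shared peaks were counted.

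**Figure D3:**
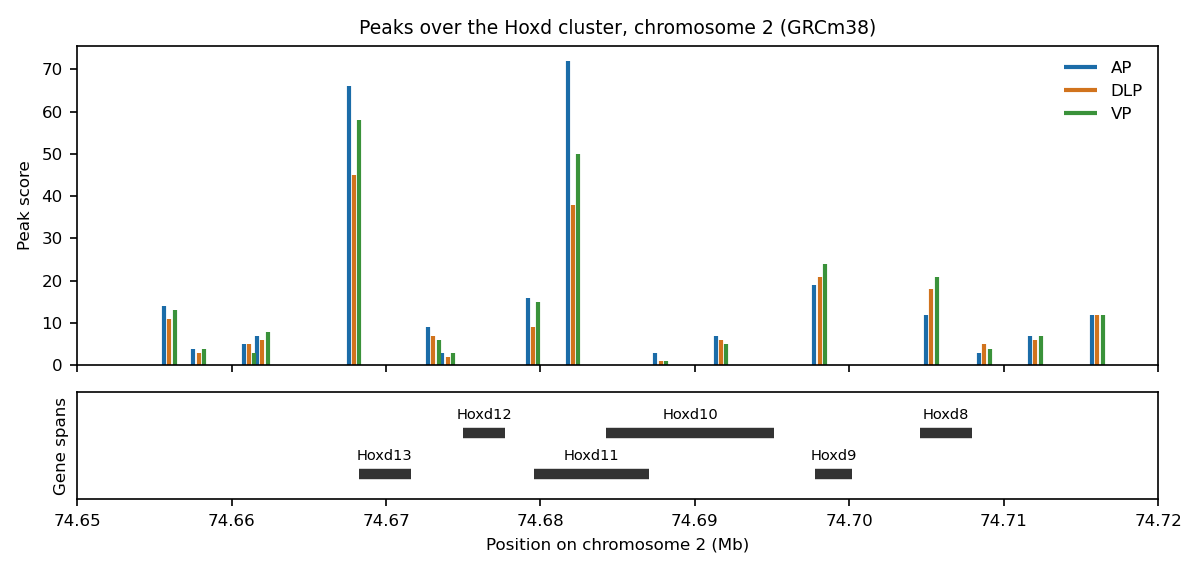
Peak scores (y axis) along the Hoxd cluster on chromosome 2 (x axis, GRCm38 position in Mb), 1 line per library at each peak, set slightly apart sideways so that they can be seen, with gene spans below. Scores over the strongest peaks are lower in DLP than in AP and VP, as in the summed scores of Hoxd11 (196 in AP, 126 in DLP and 160 in VP).

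Fibroblast genes were the other list that stood apart in DLP minus AP, with a median of -0.11 at percentile 1.74 and 4 of 9 genes higher. Of its 29 different peaks, 13 were higher and 13 lower. These genes had few and weak peaks, such as Fbn1 with 9 in AP and 5 in DLP and Pdgfrb with 8 and 12. The percentile was 41.1 with the strongest peak of each gene, and with scaling to control promoters the median was 0.15 at percentile 2.36. Proximal progenitor-like luminal genes were higher in DLP in 10 of 13 cases, with a median of 0.29 at percentile 97.0, inside the range. Cldn10 had 38 in AP and 62 in DLP, and Psca, a stem cell antigen of the prostate, had 15 and 24. With the strongest peak of each gene this list lay at percentile 97.8, and with a pseudocount of 5 at 98.7. The list of NF-kB pathway and target genes had 19 of 32 members higher, with a median of 0.14 at percentile 85.5. Csf2, which encodes the cytokine GM-CSF, had 14 in AP and 49 in DLP over 4 peaks (2.66-fold) and Traf1 had 6 and 14 (2.03-fold), whereas Ripk2 had 282 and 169 and Nfkbib 85 and 68. AP-1 and immediate early genes lay at percentile 96.6 by the mean of their peaks and at 0.09 by the strongest peak of each gene. Egr1, which was lower by the mean as well (log2 difference -0.48), had summed scores of 688 in AP and 486 in DLP. The AP-1 list lay at 62.2 in VP minus AP and, in VP minus DLP, at 3.24 by the mean and 97.9 by the strongest peak. Trp63, the basal cell transcription factor gene, had 30 and 44 (log2 difference 0.68). Over all kept peaks 5878 were higher in DLP and 1541 lower, against simulated maxima of 1979 and 2019 with the AP step and 6363 and 6346 with 1 read worth 1 unit. The higher share was 79.2%, but 49.1% after removal of the trend with signal, 51.4% with quantile-normalized values and 94.98% with scaling to control promoters. At a score of at least 20, 232 were higher and 100 lower, and 210 and 100 with the trend removed. Simulated maxima there were 9 and 10 with the AP step and 234 and 232 with 1 read worth 1 unit. The 232 higher peaks thus did not exceed the maximum with 1 read worth 1 unit, a setting that overstates counting error in AP. The 100 lower peaks lay under the mean of 198 at that setting. Staying under its maximum therefore does not show that counting error made the 232.

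The comparison of VP with DLP, the lobes that lay furthest apart, asked how the VP lobe differed from the DLP lobe. Innate immune sensing genes were lower in VP in 25 of 32 cases, with a median of -0.42 against -0.18 for random lists, at percentile 1.13. Il18, an inflammasome-processed cytokine gene, had 21 in DLP and 4 in VP over 3 peaks, and Il1rn had 55 and 10 over 6 peaks (3.33-fold lower), while Irak1 had 23 and 28. Mucosal defence genes had a median of -0.60 at percentile 2.46, with 9 of 16 lower. Slpi, a secreted protease inhibitor gene, had 66 and 22 (2.44-fold lower), and S100a8 had 4 and 1, whereas Ccl28, a mucosal chemokine gene, had 23 and 55 (2.22-fold higher). Neither list stood apart when peaks at gene ends alone were used, at percentiles 8.6 and 10.7. After quantile normalization they were at 4.16 and 0.9, and with each peak counted for its nearest gene at 2.8 and 2.03. With the strongest peak of each gene, mucosal defence genes lay at 18.3. Markers of myeloid cells lay at percentile 5.33, with 6 of 10 lower, and those of lymphocytes at 77.4.

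Posterior Hox genes were higher in VP than in DLP in 10 of 13 cases, with a median of 0.16 at percentile 98.99, but 97.36 with each shared peak counted for its nearest gene and 90.2 with peaks at gene ends alone. Hoxb13 had 97 in DLP and 128 in VP (1.36-fold) and Hoxa10 had 36 and 51, while Hoxb9 had 38 and 31. With scaling to control promoters, which moved the median of all peaks to -0.20, the Hox median was -0.02 at percentile 98.97. Lobe-restricted secretory genes had a median of 0.24 at percentile 99.5, with 5 of 9 higher. Msmb, a gene of a secreted prostate protein, had 13 and 38 over 3 peaks (2.11-fold) and Pbsn, the probasin gene, 7 and 11, whereas Crabp1 had 35 and 20. Over the list's 36 different peaks the mean was -0.01, with 19 higher and 16 lower. Its percentile was 95.1 with the strongest peak of each gene and 92.8 after quantile normalization. Smooth muscle genes had a median of 0.20 at percentile 98.6, with 4 of 7 higher and 3 lower. Acta2 had 50 and 82 and Lmod1 111 and 137, whereas Des had 61 and 52 and Myocd 4 and 1. With the strongest peak of each gene the list lay at percentile 24.5.

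Other genes with large VP and DLP differences belonged to lists inside the central range. Proximal progenitor-like luminal genes were lower in VP in 11 of 13 cases, with a median of -0.36 at percentile 11.7. Psca had 24 in DLP and 6 in VP (3.16-fold lower) and Wfdc2 had 219 and 95 (2.57-fold lower), whereas Ly6a had 9 and 13. With peaks at gene ends alone the list lay at percentile 0.385. NF-kB pathway and target genes lay at percentile 22.7, with 19 of 32 lower, Csf2 at 49 and 11 and Cxcl10 at 124 and 191; with the strongest peak of each gene the list lay at 0.62. Of the genes of NF-kB subunits, mean log2 differences were 0.18 for Nfkb1, 0.08 for Nfkb2, -0.21 for Rela and -0.25 for Relb, and -0.24 for Rel, which was added after its value was seen. The inhibitor genes Nfkbia and Tnfaip3 had 0.06 and -0.26, against a list median of -0.22. Developmental regulators lay at percentile 95.4, with Barx2 at 153 and 69, Tbx5 at 10 and 17 and Tbx4 at 5 and 12. Androgen-regulated genes lay at 79.9, or 99.6 with each peak counted for its nearest gene, with Pmepa1 at 347 and 164 and Mme at 36 and 54. Over all kept peaks 2897 were higher in VP and 11891 lower, against simulated maxima of 2008 and 2008 with the AP step and 6390 and 6348 with 1 read worth 1 unit. The higher share was 19.6%, but 48.5% after removal of the trend with signal and 38.8% with quantile-normalized values, and 9.79% with scaling to control promoters. At a score of at least 20, 411 were higher and 899 lower, and 294 and 1011 with the trend removed. Simulated maxima there were 11 and 11 with the AP step and 227 and 241 with 1 read worth 1 unit.

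**Figure D4:**
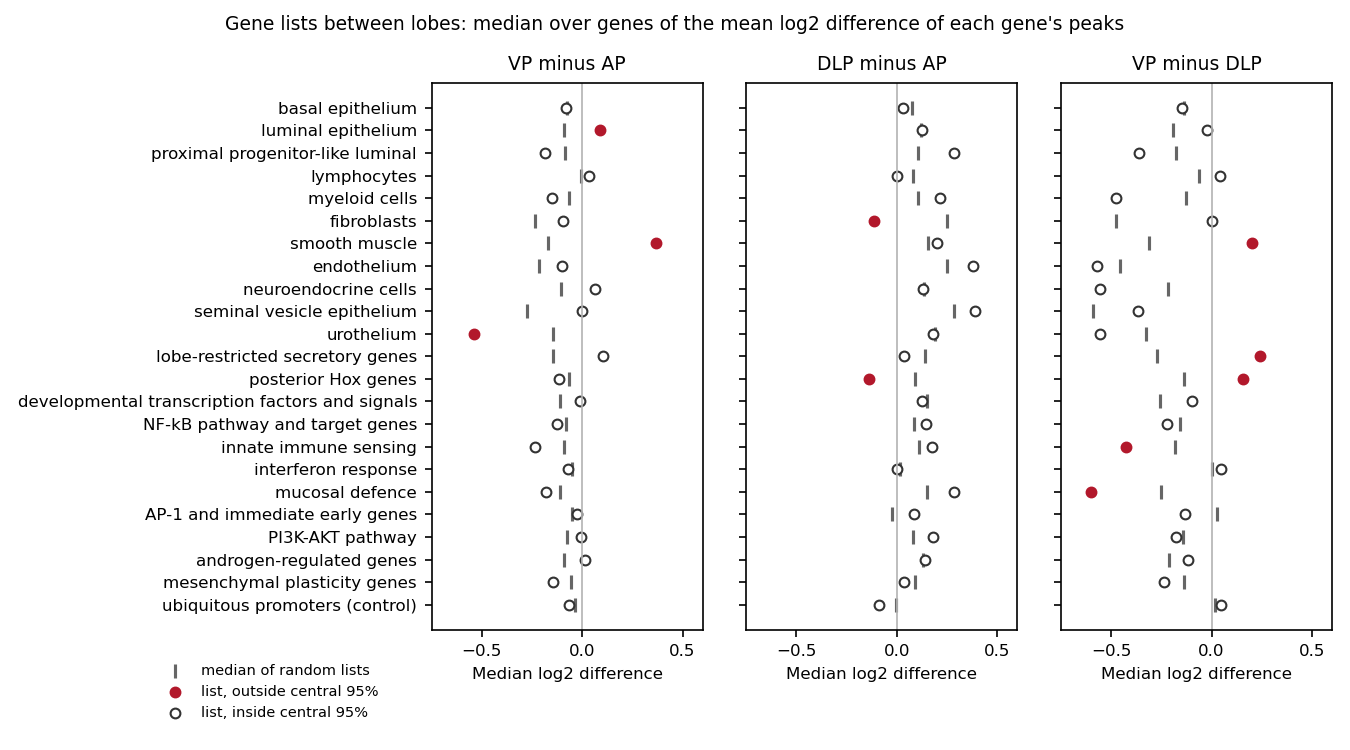
Median log2 difference (x axis) of each of 23 gene lists (y axis) in the 3 pairwise comparisons, with 1 library per lobe. Filled points lie outside the central 95% of 10000 matched random lists, open points lie inside, and the vertical ticks mark the median of the random lists. Of 69 comparisons, 10 are filled.

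In all, 10 of the 69 list comparisons lay outside the central 95%, where 3.45 would by chance. The 69 are not independent: the 3 comparisons use the same libraries, and some lists share genes or peaks. The excess over 3.45 is therefore not a measure of evidence. Percentiles of lists not yet described are given in the order VP minus AP, DLP minus AP and VP minus DLP. Endothelial markers lay at 72.8, 82.9 and 28.8, the last being 1.56 with the strongest peak of each gene, with Flt1 at 20 in AP, 55 in DLP and 14 in VP within 50 kb. Neuroendocrine markers lay at 81.3, 49.3 and 12.0, and the 3 measured seminal vesicle genes at 80.3, 64.9 and 68.4. Interferon response genes lay at 39.1, 39.0 and 73.5, with Xaf1 at 10, 14 and 4 and Ifit2 at 39, 27 and 59. PI3K-AKT pathway genes lay at 81.8, 94.4 and 33.1, with Akt2 at 148, 175 and 127. This list passed the limit in VP minus AP with the strongest peak of each gene, at percentile 100 (median 0.29 against 0), and in DLP minus AP with no distance limit, at 98.2, and with a pseudocount of 5, at 97.98. Mesenchymal plasticity genes lay at 21.4, 29.6 and 27.2, with Snai2 at 54, 33 and 39. The ubiquitous control promoters lay at 33.3, 13.3 and 60.4, the DLP minus AP value being 1.15 with peaks at gene ends alone and 2.1 with the strongest peak of each gene. Among luminal genes with small differences, summed scores were 418, 440 and 427 for Krt8 and 250, 257 and 271 for its neighbour Krt18, which shares peaks with it. They were 103, 83 and 104 for Nkx3-1 and 23, 29 and 28 for Ar, the androgen receptor gene. Tacstd2 had 137, 123 and 120, and Krt4 had 84, 80 and 70.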

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

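No paired analysis was possible because each lobe had 1 library and the comparisons came from no test. The minimum score of 20, the 3 kb limit, the comparison of gene-end shares with peaks of like signal and, for gene lists, quantile normalization, the pseudocount of 5, the scalings by median of ratios and to control promoters and the nearest-gene assignment, and for pairwise counts quantile normalization, were chosen after the data were seen. Motif content, correction for GC content, a counting interval per peak, and thinning to equal depth were not run, the first 2 for lack of a genome sequence here and the others because the scores are not counts. Depth limits weak peaks most: 371 of 416 peaks higher in AP, 3134 of 4052 in DLP and 648 of 1013 in VP had a highest score under 10. Counts of calls moved by over 1.5 times as follows, and unless stated the cause was not tested. A pseudocount of 0.1 and no filter moved no count that far.

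With equal totals, 142 peaks were higher in AP and 601 in VP, 4147 lower in VP than AP, 672 lower in DLP than AP and 1697 higher in VP than DLP. With median of ratios, 2204 were higher in DLP than in both others and 3289 higher in DLP than AP. The factors of these scalings span only 0.019 and 0.031 on the log2 scale but break ties, since 274 of the 416, 1847 of the 4052 and 531 of the 1013 peaks lay exactly 2-fold above the next lobe. With control promoters, 90 were higher in AP and 557 in VP, 4022 lower in VP than AP, 419 lower in DLP than AP and 1394 higher in VP than DLP. With quantile normalization, 1486 were higher in DLP, 4188 lower in VP than AP, 2380 higher in DLP than AP and 6664 lower in VP than DLP. With the trend on signal removed, 2803 were lower in VP than AP, 2118 higher in DLP than AP, and 4840 higher and 5133 lower in VP than DLP.

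Stricter settings lowered all counts by construction. In the order higher in AP, DLP and VP than both others, then higher and lower in VP than AP, in DLP than AP and in VP than DLP, a pseudocount of 5 gave 5, 360, 84, 288, 670, 509, 55, 441 and 3005. A filter at the 50th percentile gave 66, 1140, 424, 1014, 2212, 1550, 453, 1299 and 3801. A 4-fold threshold gave 1, 283, 7, 205, 629, 669, 23, 89 and 2834. A minimum score of 20 gave 6, 188, 99, 204, 518, 232, 100, 411 and 899. The 1.5-fold threshold raised the first 8 to 1739, 8564, 3400, 7782, 13509, 12395, 5446 and 7342. DLP had the most lobe-high peaks and AP the fewest in each of these 5 settings. Within 3 kb of a gene end lay 14.5%, 10.8% and 12.1% of peaks higher in AP, DLP and VP, a wider window by construction.

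Among gene lists, the 3 scalings changed no side of the central range in any of 69 comparisons. Each applies 1 factor per library, which moves a list and its random lists nearly alike. That result was therefore nearly fixed in advance and is no check of the lists. With control promoters 3 of the 10 medians outside the range changed sign. Percentiles that changed side follow, with causes not tested. With peaks within 1 kb of a gene end, VP minus AP became 95.9 for luminal, 2.47 for proximal progenitor-like and 15.7 for urothelial genes. DLP minus AP became 33.3 for fibroblasts and 1.15 for control promoters. VP minus DLP became 0.385 for proximal progenitor-like, 93.1 for smooth muscle, 90.2 for posterior Hox, 8.6 for innate immune sensing and 10.7 for mucosal defence genes. With no distance limit, luminal VP minus AP became 96.99, fibroblast VP minus DLP 99.99, mucosal VP minus DLP 2.99 and PI3K-AKT DLP minus AP 98.2. With quantile normalization, VP minus DLP became 97.7 for fibroblasts, 92.8 for lobe-restricted secretory, 4.16 for innate immune sensing genes, and innate VP minus AP 2.1. With a pseudocount of 5, luminal VP minus AP became 97.1, secretory VP minus AP 98.7, innate VP minus AP 1.89, proximal progenitor-like DLP minus AP 98.7 and PI3K-AKT DLP minus AP 97.98.

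The strongest peak of each gene moved the most. Smooth muscle changed direction, to 30.5 in VP minus AP and 24.5 in VP minus DLP, and so did AP-1 and immediate early genes, to 0.09 in DLP minus AP and 97.9 in VP minus DLP. VP minus AP became 51.5 for luminal, 3.18 for urothelial and 100 for PI3K-AKT genes. DLP minus AP became 97.8 for proximal progenitor-like, 41.1 for fibroblast, 1.21 for secretory and 2.1 for control genes. VP minus DLP became 1.56 for endothelial, 95.1 for secretory, 0.62 for NF-kB and 18.3 for mucosal defence genes. With each peak counted for its nearest gene, VP minus AP became 96.1 for luminal and 15.7 for urothelial genes, DLP minus AP 12.0 for fibroblast, 0.415 for secretory and 4.45 for posterior Hox genes, and VP minus DLP 97.36 for posterior Hox, 2.8 for innate immune sensing and 99.6 for androgen-regulated genes. None of the 10 comparisons outside the range stayed outside it under all 9 alternatives.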

Other observations

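All tests in this part were chosen after the results were seen, and the limits for the patterns of DLP peaks and of immune lists were redrawn after their values were known, those of the immune lists 2 times. The X chromosome stood apart from the autosomes in every pair of lobes, most in those with DLP. Its peaks held 1.26% of the DLP total against 1.37% in AP and 1.42% in VP. The ratio of DLP to AP totals was 0.905 on chromosome X and 0.959 to 1.01 over the 19 autosomes, and the ratio of DLP to VP totals was 0.877 against 0.966 to 1.03. The ratio of VP to AP totals was 1.033 against 0.959 to 1.024, only just outside. It follows from the other ratios, so the pairs are not separate results. Chromosome X held 1058 kept peaks, fewer than any autosome. Egr1 and Junb, the lowest of the immediate early genes in DLP minus AP, had strong peaks: the summed scores of Egr1 were 688 in AP, 486 in DLP and 638 in VP, and those of Junb were 324, 232 and 295.

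The first pattern was that more peaks were higher in DLP than in both other lobes. A weaker contrast between strong and weak peaks in the DLP library could raise its weak peaks. Among peaks with a highest score of at least 20 the DLP count was 188 before and after quantile normalization. Its ratio to the next lobe's count rose from 1.90 to 2.76 because the VP count fell from 99 to 68. The 90th percentile of scores was 34 in DLP, 35 in AP and 37 in VP. Quantile normalization could thus hardly lower the DLP count of such strong peaks, and it decides nothing about contrast for them. Among weaker peaks that ratio dropped to 1.40, from 4.23, so that the contrast and a lobe difference cannot be told apart there either. Unequal depth stays open, since it is unknown for DLP and VP, as does a difference between the lobes themselves, which no replicate tests.

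The second pattern was the score of 350 in AP at the peak in Cwc27. A regional gain of copies in the AP library would raise the neighbouring peaks too, but the 6 other kept peaks within 500 kb had a median log2 difference of -0.25 and a maximum of 0.26, against 3.21 for the peak itself. Reads stacked on a narrow repeat or an amplified fragment remain a candidate explanation: the peak ranked 1 among kept peaks by AP score per kb of width, at 983 against a median of 12.9. A strong regulatory element would rank high too, so the 2 cannot be told apart from these scores. In DLP the same peak ranked 1204, and a difference between lobes was not tested.

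The third pattern was that the innate immune sensing and mucosal defence lists were lower in VP than in DLP. Weaker contrast in the DLP library cannot be told apart from another cause. Mucosal defence lay at percentile 0.9 after quantile normalization, but at 18.3 with the strongest peak of each gene and 10.7 at gene ends. What weaker contrast alone would do to the last 2 percentiles was not tested. Innate immune sensing lay at 4.16 after quantile normalization, inside the range, but at 1.77 with the strongest peak of each gene. Fewer lymphocytes or myeloid cells in the VP library may also lower such genes. Lymphocyte markers lay at percentile 77.4 with 5 of 9 genes higher in VP, and myeloid markers at 5.33 with 4 of 10 higher, and members going both ways decide neither. A difference in lobe epithelium stays open and untested.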
